A study of Arabidopsis thaliana with 12 samples.

How the data were processed

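The series compared transcript levels in Arabidopsis thaliana, wild type of the ecotype Columbia 0, measured on arrays from total RNA. The part of the plant used was not given in the sources used here. Per the labels, 6 control samples came from plants grown in light at 80 µE and 6 recovered samples from plants exposed to 1000 µE for 1 h and then kept at 80 µE for 48 h. Group and replicate number were taken from the sample titles, and every sample of the series was used. No label says that samples of a group came from separate plants or cultures, so p-values measured only the spread between these samples, which may be technical.

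The deposited values were intensity values on a linear scale, with 1 value for each of 3439 probes in each sample. They were never negative, and 11 of 12 samples had a maximum of 100, while recovered 4 had a maximum of 90.5. The background correction, the scaling and any averaging of spots behind the deposited intensity values were not given in the sources used here, so neither the scale of a value nor its distance from the array background is known. The number of per-sample columns left unused was 0. The number of arrays limits the precision of all comparisons.

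The log2 medians of the samples spanned 1.23, so the values were quantile normalised between arrays. Values below 0.0322, the 5th percentile of all positive values, were set to that floor, and log2 was taken. A probe was tested where at least 6 of the 12 samples lay above the floor, which kept 3177 probes and left out 262. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, recovered minus control), and a probe was called at a Benjamini-Hochberg adjusted p under 0.05. Probes were tested separately. Fold changes were 2 to the power of the difference between group means of log2 values, with 95% confidence intervals from the limma fit, and they are relative to the quantile-normalised distribution.

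Gene names were taken from a table that pairs the probes with the platform's annotation. It gave 1 gene for 692 probes, several genes for 870 and none for 1877, and a name is printed only for a probe with 1 gene. These 692 probes covered 689 loci, and 2 of them were not matched to the RefSeq gene table of assembly TAIR10.1, used for current symbols. The build behind the array was not given in the sources used here, so no coordinates are printed. Probe sequences were not used here, so probes of gene families with near-identical members may measure more than 1 member.

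The text names up to 12 genes higher and up to 12 lower, taken by largest absolute log2 fold change among called probes with 1 gene, and up to 4 members of each of 21 gene lists by smallest p. The ELIP genes and reference genes were to be named wherever measured. The lists, the naming rule, the test, the floor and all alternatives except those named last below were fixed before the data were examined. The lists held 342 members: photosystem I, photosystem II, light-harvesting antenna, light-stress LHC-like and quenching, electron transport and ATP synthase, Calvin cycle, photorespiration, chlorophyll biosynthesis, carotenoids and tocopherol, plastid ribosomal proteins, antioxidant and thioredoxin systems, plastid proteases, chaperones, plastid protein import, plastid sigma factors, starch and sugar transport, fatty acids and galactolipids, amino acids, phenylpropanoids, other leaf cell types and reference genes. Lists with at least 3 tested loci were compared by camera of limma with all other tested probes, named or not, with probes of a named locus merged. Of the 3177 tested probes, 629 had a named locus. The correlation was preset at 0.01, and the test was run again with an estimated correlation. Adjusted p-values of the list tests cover the 2 lists that could be tested. The fry test of limma asked whether the genes of a list moved one way on balance, without setting them against other genes.

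Both groups carry the replicate numbers 1 to 6. Whether the numbers pair the samples was checked by correlating the deviations of same-numbered samples from their group means over the tested probes. The correlation lay between 0.111 and 0.487 for the 6 pairs, and each of the 12 samples was best matched in the other group by its own number, so the numbers were taken to pair the samples. The pairing comes from the data and the numbers in the titles, and no label names a shared plant pool, membrane or day. The main fit was fixed beforehand without this pairing, so SEs, intervals and p-values come from an unpaired fit unless another fit is named. A fit with the number as a block is given beside a result where it changed a call. Genes were named from the main fit, so probes called only with the block are not named.

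The procedure was tested on simulated data for 3177 probes, 200 of them changed, in 10 draws. With independent errors and 6 samples per group, 23.5% of probes changed 2-fold and 69.6% of those changed 4-fold were recovered, and 6.19% of the calls were false. With errors shared within adjacent replicate numbers as measured here, 46.5% of the calls from 6 samples per group were false. The simulations left out what same-numbered samples of the groups share.

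Alternatives covered the scaling between arrays, the floor, a pseudocount, the filter on dim probes, the replicate block, array weights, a variance trend, the threshold, an exact rank-sum test, other list tests and the removal of each sample. Averaging adjacent replicate numbers, treating them as a random block, the replicate block with an estimated correlation and leaving out samples 3 and 4 of either group or both samples of a number were chosen after seeing the data.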

Results

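Transcript levels were measured with a gene array in 12 samples of wild-type Arabidopsis. The 6 control samples came from plants in normal light of 80 µE, and the 6 recovered samples from plants that had spent 1 h in light of 1000 µE followed by 48 h at 80 µE. The sum of the deposited intensities ranged from 2874 in control 5 to 3406 in recovered 2. The log2 median ranged from -2.35 in recovered 4 to -1.13 in recovered 1, and between 82.3% and 93.1% of the probes lay above the floor.

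Samples with adjacent replicate numbers (1 and 2, 3 and 4, 5 and 6) were closer to each other than to the rest of their group. Pearson's r across probes, which are not independent replicates, was 0.854 to 0.939 within these adjacent pairs and 0.650 to 0.794 between other samples of a group. Between the groups r ranged from 0.611 (control 4 with recovered 2) to 0.859 (control 2 with recovered 2). It was 0.858 for control 1 with recovered 1, and both lay above the 0.854 of the adjacent controls 5 and 6. Samples of different treatment can thus be as close as an adjacent pair. For 12 of 12 samples the closest sample of all was the adjacent number. The SDs, SEs, intervals and p-values from 6 samples per group treat adjacent numbers as separate samples. If these are repeat readings, the SEs and p-values are too small and the intervals too narrow. The count of calls is therefore also given with adjacent numbers averaged to 3 values per group.

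**Figure D1:**
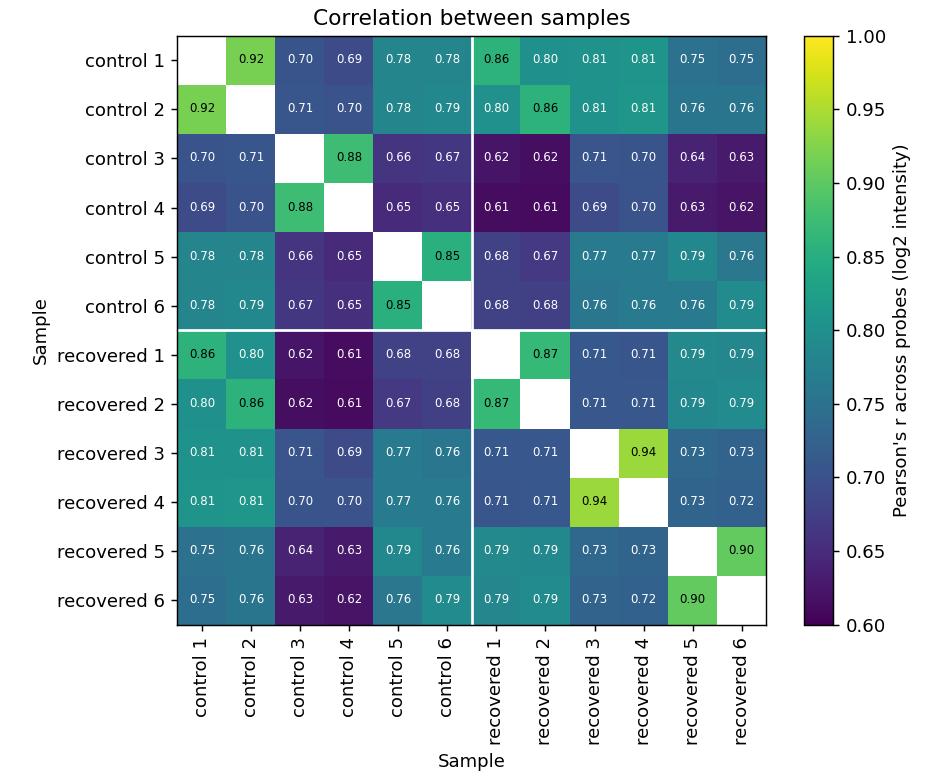
Pearson's r across tested probes between the log2 quantile-normalised intensities of all samples, with samples on both axes, r written in each cell and shown as colour, and white lines between the groups. Adjacent replicate numbers form bright cells with r of 0.854 to 0.939, and other samples of a group reach at most 0.794. Between the groups r reaches 0.859, for control 2 with recovered 2.

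The comparison asks which transcripts differed between control plants in normal light and plants 48 h after the light stress. The sample titles mark the controls as the starting time, and no label names a control kept for the same time. A difference can thus come from the light stress or from plant age and time of harvest, which cannot be told apart here. Among probes with 1 gene, 9 genes were called higher and 7 lower with 6 samples per group. With adjacent numbers averaged or used as a random block, 0 of these 16 genes were called. The largest increase among them was that of AT5G58330, the NADP-dependent malate dehydrogenase, which exports reducing equivalents from the chloroplast as malate. Its log2 intensity was -0.99 ± 0.37 (SD, n = 6) in control and 1.32 ± 0.70 (n = 6) in recovered samples, a 4.94-fold difference (95% interval 3.02 to 8.10, adjusted p = 0.00362), although control 2 at -0.25 stood apart from the other controls. With adjacent numbers averaged, the SE of its log2 fold change of 2.31 was 0.47 against 0.33, and limma gave an adjusted p of 0.629. CCL (AT3G26740), a CCR-like gene with a clock-controlled transcript, rose from 1.32 ± 0.40 to 3.21 ± 0.32, or 3.71-fold (2.54 to 5.42, adjusted p = 0.00349). With array medians aligned its log2 fold change of 1.89 became 1.28 and the call was lost (adjusted p = 0.131). The strongest decrease among them was that of AT2G36480, from 1.37 ± 0.85 to -1.67 ± 0.90, or 8.18-fold (4.03 to 16.6, adjusted p = 0.00591). Its size differed between adjacent pairs. In samples 3 and 4 the controls were at 0.27 and 0.41 and the recovered samples at -0.56 and -0.57. The other controls lay at 1.54 or higher and the other recovered samples at -1.78 or lower.

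AT3G13150 and AT3G26630, also called higher, encode pentatricopeptide repeat proteins, of a family that binds organellar RNA. The family was not among the fixed lists and was not tested as a group. AT3G13150 had a log2 fold change of 1.56 (SE 0.27, adjusted p = 0.0113) and AT3G26630 one of 1.45 (SE 0.33, adjusted p = 0.0438). The call of AT3G26630 was lost with the deposited scaling kept (adjusted p = 0.0575), with array medians aligned (0.181) and with cyclic loess (0.0656), and it was made in 1 of 12 fits without a single sample. AT5G52810, the SARD4 reductase of pipecolic acid synthesis, was 2.60-fold higher (adjusted p = 0.0104). AT1G35510, of the O-fucosyltransferase family, was 2.56-fold higher, and the kelch-repeat F-box gene AT4G39760 was 2.40-fold higher. AT1G67800, of the copine family, was 2.34-fold higher. The smallest increase was that of the chromatin remodelling gene chr31 (AT1G05490), at 1.98-fold (adjusted p = 0.0498). In each of these 9 genes the 6 recovered samples lay above the 6 controls.

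Among the 7 genes that were lower, AT-HF (AT4G26900) encodes an enzyme of histidine biosynthesis. It was 3.82-fold lower (adjusted p = 0.0450), its groups overlapped, and the call was lost with the replicate number as a block (adjusted p = 0.0716). AT5G10920, the argininosuccinate lyase gene of arginine biosynthesis, was 2.31-fold lower (adjusted p = 0.0442, with the block 0.0519), and recovered 5 at -1.62 stood apart from its group. AT1G02020, of the nitroreductase family, was 3.44-fold lower (adjusted p = 0.0387, with the block 0.0636). It fell least in samples 5 and 6, from -0.67 to -1.26 and from -1.02 to -1.16. The remaining genes were AT3G56290, 3.56-fold lower (adjusted p = 0.00362), AT2G46630, 3.34-fold lower (adjusted p = 0.00349), and AT3G09050, 2.01-fold lower (adjusted p = 0.0321). Apart from AT-HF, the groups of these genes did not overlap.

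AT5G58330, AT3G13150, AT5G52810, AT2G36480 and AT2G46630 were called with each of the 4 scalings. Of the other genes, AT3G26630, AT1G35510, AT1G67800, chr31, AT-HF, AT3G56290, AT1G02020, AT5G10920 and AT3G09050 lost the call with the deposited scaling kept. With array medians aligned, CCL, AT4G39760, AT3G26630, AT1G35510, AT1G67800 and chr31 lost it. There the log2 fold change of chr31 fell from 0.99 to 0.57 and that of AT4G39760 from 1.26 to 0.76. With cyclic loess, AT3G26630, chr31, AT1G02020 and AT5G10920 lost it. AT5G58330, CCL, AT3G56290 and AT2G46630 were called with any single sample, or both samples of any 1 number, left out. Such removals leave the adjacent number in the fit, so they cannot show whether a call rests on 1 adjacent pair. With adjacent numbers averaged, limma called none of these genes (adjusted p = 0.629 to 0.705).

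**Figure D2:**
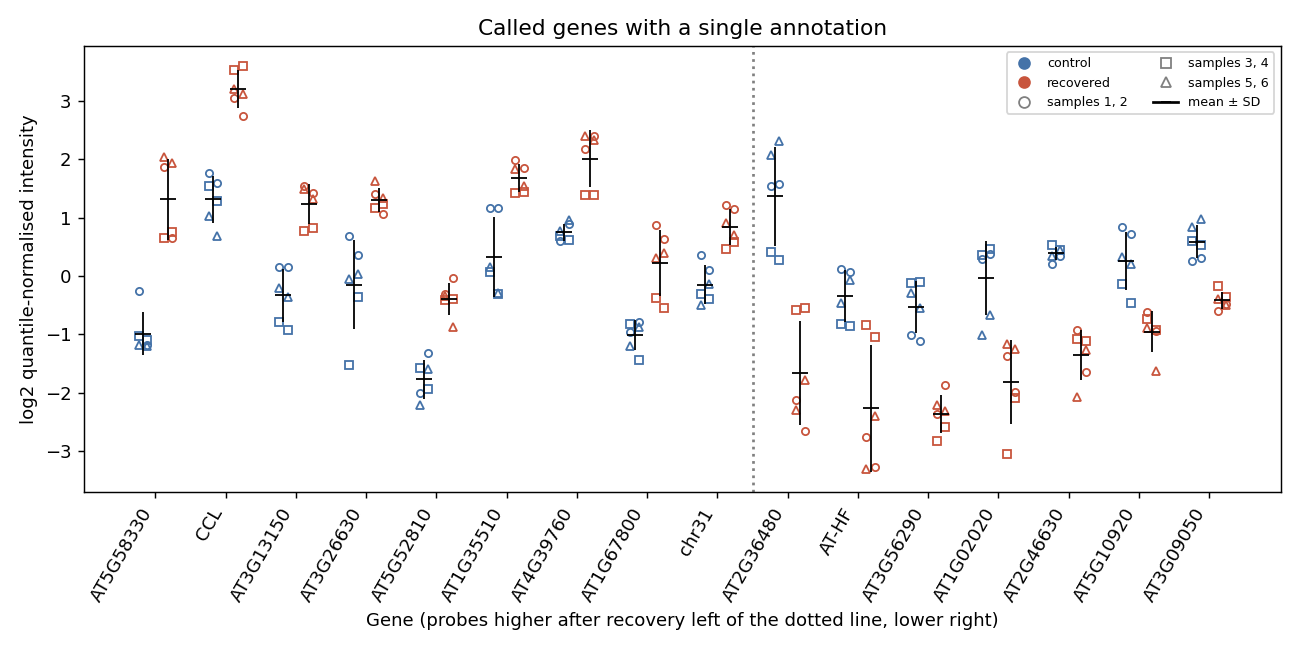
Log2 quantile-normalised intensity (y axis) of the 16 called genes with a single annotation (x axis), with 1 point per sample, control in blue and recovered in red, marker shapes for adjacent replicate numbers, and bars for mean ± SD of 6 samples. AT2G36480 falls from 1.37 to -1.67 and CCL rises from 1.32 to 3.21, and points of adjacent numbers often lie close together.

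Over all 3177 tested probes, limma called 69, or 2.17%, with 28 higher and 41 lower after recovery. The groups did not overlap for 151 of the tested probes, where chance gives 0.216%, or 6.88, if all 12 samples are independent, which the closeness of adjacent numbers leaves in doubt. Fold changes of called probes ran from 1.72 up to 7.34 for higher and 8.33 for lower probes, with a median of 2.60. The extremes were unnamed probes, picked after their values were seen: probe 2235 had a log2 fold change of 2.88 (SE 0.45, adjusted p = 0.00591) and probe 4341 one of -3.06 (SE 0.36, adjusted p = 0.00349). The number of probes with an unadjusted p under 0.05 was 580, where chance gives 159. Of the 69, 16 had 1 gene, 11 had several genes and 42 had none. With adjacent replicate numbers averaged to 3 values per group, limma called 0 probes (lowest adjusted p = 0.629), and 164 of 3177, or 5.16%, had an unadjusted p under 0.05. With adjacent numbers as a random block, 1 probe was called, probe 4341 (adjusted p = 0.0411), with 268 at an unadjusted p under 0.05.

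Higher probes made up 40.6% of the calls (exact binomial 95% interval 28.9 to 53.1, for description only). The interval treats called probes as independent, although all were measured in the same samples, and leaves out the choice of scaling. The share of higher probes was 82.9% (29 higher, 6 lower) with the deposited scaling kept, where the median log2 fold change of all probes was 0.47. It was 23.9% (17 higher, 54 lower) with array medians aligned. With the replicate number as a block, 42 probes were higher and 43 lower, and 46 of the 69 calls were kept.

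Of the 342 members of the gene lists, 20 were on the array with a probe of their own, 19 were tested and 0 passed over all probes, with 3 at an unadjusted p under 0.05. The plastid ribosomal proteins, nuclear-encoded parts of the chloroplast translation machinery, had 5 tested members, none of which passed over all probes. All 5 had values below 0, with a median log2 fold change of -0.54. The lowest was RPL17 at -1.16 (SE 0.36, adjusted p = 0.115, and 0.0333 adjusted over the list alone). It passed over all probes with array weights (adjusted p = 0.0257) and without recovered 3 and 4 (adjusted p = 0.0164). RPS10 was at -0.59. Recovered 2 lay far below the rest at -4.33 and control 2 was the lowest control at -2.92, and RPS10 was at -0.08 without recovered 2 alone and at -0.43 without both. RPL34 was at -0.54, RPS6 at -0.53 and RPL5 at -0.16. The value of RPS6 rests partly on the floor, where samples 5 and 6 of both groups lay, and it was at 0.03 without controls 3 and 4. RPL34 was at 0.23 and the list's median at -0.02 with the deposited scaling kept, against 0.47 for all probes. Against all other tested probes the list was not called by camera (adjusted p = 0.113, and adjusted p = 0.214 with an estimated correlation). With the replicate number as a block camera called it (adjusted p = 0.0324), but not with an estimated correlation (adjusted p = 0.115). The directional fry test sets the list against no change and not against other probes. It gave an adjusted p of 0.0474, and an unadjusted p of 0.176 with adjacent numbers averaged. RPL29 was on the array and not tested.

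Photosystem II had 3 tested subunits, none past the threshold, with log2 fold changes of 0.35 for PSBW, -0.44 for PSBY and -1.17 (SE 0.76) for the assembly factor PSB27. In PSBY and PSB27 the recovered sample lay below the control of the same number in 6 of 6 pairs, and neither gene passed with or without the block. Among members of other lists, RPL17 also lay below in 6 of 6 pairs and DHAD above in 6 of 6, and neither passed with the block. If adjacent numbers are repeat readings, the 6 pairs hold only 3 separate comparisons. The share of all tested probes with 6 of 6 was not computed, so these counts are not known to be unusual. Without controls 3 and 4, PSBY was at 0.06. Leaving out a single sample put PSBY, the list's median with all samples, between -0.84 without control 6 and -0.01 without recovered 6. The list's median of -0.44 was not called by camera (adjusted p = 0.704, and adjusted p = 0.709 with an estimated correlation) or by fry (adjusted p = 0.580). The photosystem I subunit PSAN was at 0.03 (SE 0.28), and the antenna gene LHCB1.5 (AT2G34420), which has near-identical family members, at 0.23 (SE 0.21). With array medians aligned, PSBW was at -0.29, PSAN at -0.63 and LHCB1.5 at -0.53, none past the threshold, and PSAN was at -0.07 with the deposited scaling kept and with cyclic loess.

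In the Calvin cycle, PRK, the phosphoribulokinase gene, had a log2 fold change of -0.67 (SE 0.23). It did not pass over all probes (adjusted p = 0.143), but did when adjusted over the 2 tested genes of its list alone (0.0230). That adjustment was made for each list separately and leaves the number of lists out of account. With adjacent numbers averaged, limma gave PRK an unadjusted p of 0.145. SBPASE was at 0.06 (SE 0.75), with control 6 far below the other controls at -4.60 and recovered 6 lowest of its group at -3.09. It was at -0.61 without control 6 alone and at -0.23 without both. DHAD, an enzyme of branched-chain amino acid synthesis, was at 1.78 (SE 0.57, adjusted p = 0.117, and 0.0151 adjusted over the 2 tested genes of its list alone). With adjacent numbers averaged, limma gave DHAD an unadjusted p of 0.0450 and an adjusted p of 0.837 over all probes. Controls 3 and 4 lay far below the other controls of DHAD, at -2.65 and -3.45, and without them it was at 0.83. KARI of the same pathway was at -0.01. CHLM and CHLP of chlorophyll biosynthesis were at 0.65 and 0.03, and CHLM was at 0.38 without control 6, which stood apart at -3.90. PRXIIE and NTRC, of the antioxidant and thioredoxin systems, were at 0.34 and 0.06, and the acyl carrier thioesterase gene FATB at 0.03. With array medians aligned, SBPASE was at -0.16, CHLP at -0.40, NTRC at -0.17 and KARI at 0.01. PRXIIE was at -0.44 with array weights and FATB at -0.33 without recovered 3 and 4, so these 6 values have no settled sign. SBPASE and NTRC also lay below 0 with cyclic loess, at -0.07 and -0.02.

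**Figure D3:**
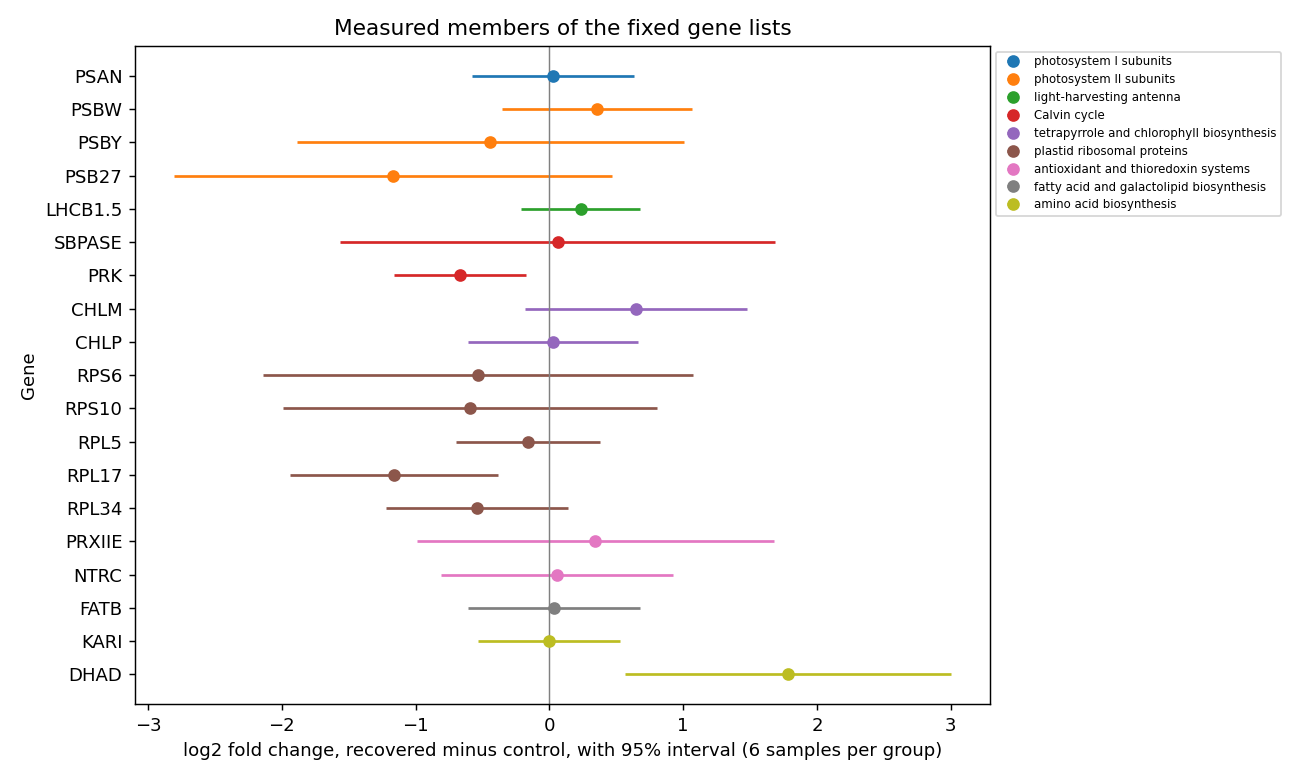
Log2 fold change, recovered minus control (x axis), of the 19 tested members of the gene lists (y axis), coloured by list, with points for the estimate and lines for the 95% interval from limma with 6 samples per group. The 5 plastid ribosomal protein genes lie between -1.16 and -0.16, and DHAD lies highest at 1.78, or 0.83 without controls 3 and 4.

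The other 12 lists had no tested member and were not analysed here. They were light-stress LHC-like and quenching genes with the ELIP genes, electron transport and ATP synthase, photorespiration, carotenoids and tocopherol, plastid proteases, chaperones, plastid protein import, plastid sigma factors, starch and sugar transport, phenylpropanoids, other leaf cell types and reference genes.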

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

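A sample far from the others of its group, by the gap to its nearest neighbour over the range of the group, was found in 5 of 74 groups of values, where chance gives about 3.7. The NADP-dependent malate dehydrogenase gene AT5G58330 had a log2 intensity of -0.25 in control 2, against -1.04 in the next control. The argininosuccinate lyase gene AT5G10920 was at -1.62 in recovered 5, against -0.94 in the next recovered sample. SBPASE was at -4.60 in control 6, and the gap to the next control took up 0.811 of the range of the controls, and recovered 6 was also the lowest of its group at -3.09. RPS10 was at -4.33 in recovered 2, against -1.90 in the next recovered sample, and control 2 was also the lowest of its group at -2.92. CHLM was at -3.90 in control 6, against -2.74 in the next control.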

How the results depend on the processing

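Averaging adjacent numbers, the random block, the replicate block with an estimated correlation and the removal of samples 3 and 4 or of both samples of a number were chosen after seeing the data. The 16 called genes kept their direction under every setting run. They were picked as called in these data, and all but AT-HF had groups that did not overlap. Leaving out or averaging samples could thus hardly turn their direction. The number still called was 7 with the deposited scaling kept, 10 with array medians aligned, 12 with cyclic loess and 0 with adjacent numbers averaged. The 28 higher and 41 lower probes became 29 and 6 with the deposited scaling kept (82.9% higher), and 17 and 54 with array medians aligned (23.9% higher). The floor at the 20th percentile gave 47 and 74, no filter on dim probes 41 and 62, array weights 92 and 147, a variance trend with robust fitting 43 and 66, and the exact rank-sum test 58 and 93. An adjusted p under 0.01 gave 6 and 7. Averaging adjacent numbers, which leaves fewer samples, gave 0 and 0 with or without a block. Adjacent numbers as a random block gave 0 and 1 (0% higher). Without recovered 3 and 4, 71 and 122 were called, and without control 3 and 4, 24 and 51, with 36 of the 69 calls kept. Aligning medians divides each array by 1 factor, although the deposited shift of recovered 1, 2, 5 and 6 was 1.27 at the 25th percentile and 0.01 at the 95th. Bright probes were lowered too: LHCB1.5 went from 0.03 with the deposited scaling kept to -0.53, and PSAN from -0.07 to -0.63. Beyond these points the cause of the changes was not tested.

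With the replicate number as a block, following the pairing, 42 probes were higher and 43 lower. The ribosomal list (median -0.54) then passed camera (adjusted p = 0.0324) but not with an estimated correlation (adjusted p = 0.115), and AT-HF, AT1G02020 and AT5G10920 lost their calls. The block changed no other call of a named gene or list. The list, reported at an adjusted p of 0.113, also passed camera with adjacent numbers averaged and blocked (median -0.54, adjusted p = 0.0401, and 0.338 with an estimated correlation) and without recovered samples 3 and 4 (median -1.14, adjusted p = 0.0408), while without control samples 3 and 4 it did not (median -0.10, adjusted p = 0.443). Averaged without a block it did not (adjusted p = 0.102). Fry, against no change, gave an adjusted p of 0.0474. The camera adjusted p ranged from 0.0324 to 0.443 over 17 settings. The cause was not tested.

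Leaving out each sample in turn gave 9 to 27 higher probes and 11 to 37 lower, with 37.5% to 55.0% higher, and 7 to 13 of the 16 genes still called. Leaving out both samples of a number gave 6 to 12 higher and 4 to 16 lower, with 42.9% to 60% higher, and 4 to 9 of the 16 genes. Leaving out any sample but recovered 3 or recovered 4 moved a count by more than 1.5 times. The total of 69 called probes fell to 40 without control 1, 32 without control 2, 24 without control 3, 23 without control 4, 34 without control 5 and 32 without control 6. It was 25 without recovered 1, 22 without recovered 2, 21 without recovered 5 and 21 without recovered 6. The median of the ribosomal list ranged from -0.82 without recovered 4 (adjusted p = 0.0467) to -0.36. The background of the arrays is unknown, so values of dim probes stay uncertain.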

Other observations

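Further genes, picked after their values were seen, did not pass the threshold with limma and 6 samples per group. Among genes of the chloroplast NADH dehydrogenase-like complex and its assembly, CRR21 had a log2 fold change of 1.06 (SE 0.33, adjusted p = 0.117), CRR41 was at 0.47, NdhN at 0.37, NdhS at 0.18 and PIFI at -0.24. CCS, the copper chaperone of superoxide dismutase, was at -1.67 (SE 0.43, adjusted p = 0.0631). GLDH, the enzyme of the last step of ascorbate synthesis, was at -0.66 (adjusted p = 0.150). CUTA was at -0.65 (adjusted p = 0.0864) with groups that did not overlap, and AT2G27290 at 1.08 (adjusted p = 0.0816). Of a pair of genes in sulphur assimilation and methionine synthesis, APS4 was at -0.89 (adjusted p = 0.175) and CBL at -1.17 (adjusted p = 0.438).

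The tests of repeat readings, of splits that keep adjacent numbers together or part same numbers, of an effect in every pair, and of the deposited medians were chosen after the results were seen. The first pattern is the 69 calls with 6 samples per group. Of 100 splits of the 12 samples into 6 and 6, 1, the real one, gave as many calls, and the highest other gave 42, but these splits treat the samples as exchangeable, which adjacent numbers are not. In separate enumerations, 4 of the 10 splits that keep adjacent numbers together gave at least 69 (highest other 196, which points to a structure of the samples), and these are too few for a share under 0.05. Of the 32 that part all 6 same-numbered samples 2 did (highest other 97), a share at which chance is not excluded. A candidate explanation that stays open is that adjacent numbers are repeat readings of one hybridisation: 20 simulated unchanged data sets with the measured pair correlation gave a median of 27 calls and up to 71. These simulations left out what same-numbered samples of the groups share, so their counts do not carry over exactly to these data. A treatment effect shown by every pair of adjacent numbers cannot be told apart from repeat readings. The averaged values called 0 probes, with 5.16% at an unadjusted p under 0.05. With the pair as a block they also called 0 probes, with 293 (9.22%, where chance gives 159) under 0.05. Simulated averages with shared errors, fitted without a block, recovered 0% of 4-fold changes.

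The next pattern is that recovered samples 1, 2, 5 and 6 had higher deposited medians than the controls. A single scaling factor per array is argued against, because the log2 shift was 1.27 at the 25th percentile and 0.01 at the 95th, a difference of 1.265. A constant added to every spot is argued against too, since the linear difference at the 75th percentile was 2.283 times that at the 25th. An effect in every recovered sample is argued against by recovered 3 and 4, whose mean log2 median lay below the lowest control median (difference -0.02306). A difference between hybridisations and an effect of recovery in part of the plants stay open as hypotheses and were not tested.

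The last pattern is the negative values of the 5 plastid ribosomal protein genes. The choice of scaling was to count as a cause if the median relative to all probes reached 0 under any scaling. It stayed below 0 under the 4 scalings. With the deposited scaling kept, the median was -0.02, and -0.498 relative to all probes. The highest relative value of -0.379 lay within the spread of matched lists. That comparison was not in the rule fixed beforehand, and its lists were drawn only from quantile-normalised values. With this added condition the choice of scaling stays open. Spot brightness was to stay open if the median lay inside the 95% interval of 10000 lists matched on intensity. It did, as the median of -0.54 lay at the 5.4th percentile, inside -0.64 to 0.72. That interval reaches above 0 as well as below it, so it shows no common drift of such probes to lower values. A place inside it shows only that 5 probes of this brightness can reach such a median by chance. An effect of recovery on these genes stays open and, with 5 genes and the adjacent-number structure, was not resolved here.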
